A study of Mus musculus with 4 samples.

How the data were processed

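The series maps poly(A) sites in the mouse genome. It holds 4 samples: 1 3'READS library of a commercial mix of 11 cell lines captured with the CU5T45 oligo, 1 library of the mix captured with oligo(dT)10-25 beads, and 2 CLIP-seq replicates of CstF64 from C2C12 cells. Per the labels' protocols, poly(A)-selected RNA was fragmented, captured on beads, ligated to adapters, amplified by 12 cycles of PCR without molecular identifiers being described, and sequenced as 72 nt reads from the 5′ end of the fragments. Per the same labels, C2C12 cells were irradiated with UV light, RNA was trimmed with RNase T1, and complexes of 85 to 150 kDa were cut from a membrane after immunoprecipitation. The submitters' processing notes name the mm9 build, Bowtie and Novoalign, without versions or roles. How reads were filtered, including whether untemplated A at the read end was required, is not given in the sources used here, and such a filter would remove internal A-rich capture before deposition.

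The deposited read counts, the only measured unit used, are whole numbers in the fifth column of each file, and no normalization is stated per the labels. In the 3'READS files each line is 1 cleavage position with its strand and count, and no position is repeated. In the CLIP files each line is 1 distinct alignment of start, end and strand with its count, of median length 35 and 36 nt. Because the deposited lines were already distinct, using every line in place of distinct alignments changes nothing by construction, and every read was counted as the alternative instead. Whether positions count from 0 or 1 is not stated, so single positions are exact to within 1 nt. On the mitochondrial genome the most used position lay within 2 nt of the annotated 3′ end at all 6 measured genes, which also fixed the strand column as the RNA strand.

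The reference given was GRCm38 with GENCODE vM21, another build than that of the files, and coordinates were not converted. Names of nuclear genes, poly(A) signals, A-rich flanks and annotated classes of nuclear sites were therefore not analysed here. Of the gene lists fixed beforehand, only that of mitochondrial mRNAs and rRNAs was measured, since the mitochondrial coordinates matched the annotation. The mitochondrial sequence was put together from its annotated transcripts.

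Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Positions of both 3'READS libraries were pooled and chained on each strand while the gap was at most 24 nt, and clusters with 3 or more reads were kept. For shared clusters the CU5T45 library was thinned at random to 3482826 reads. Abundance is in counts per 1e6 reads (CPM), with 1 CPM added before taking log2 for correlations. The ratio of shares was computed at clusters of 30 or more reads with the exact conditional binomial 95% interval, and a cluster was called 4-fold different when the ratio reached 4 in either direction and the interval excluded 1. Counts of 0 were set to 3 reads for a bound. Intervals of shares are Clopper-Pearson. No p-value was computed, because each oligo had 1 library and the CLIP replicates counted as 1 sample. Reads within 10 nt of an annotated mitochondrial 3′ end were summed per gene, and the median log2 ratio of the list was placed among 10000 random lists of nuclear clusters matched on reads. CLIP alignments were counted by midpoint, and density ratios have intervals from 1000 bootstraps over clusters. Values of the CLIP replicates are given singly and as a mean without SD.

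Named sites follow a rule fixed before the data were examined: the 12 highest and 12 lowest ratios with intervals excluding 1, the 6 clusters with most reads, the 20 clusters with most CLIP alignments in the lower replicate, the 10 largest CLIP clusters over 1000 nt from any cleavage cluster, and up to 4 members of each list. Of the 6 measured mitochondrial genes, mt-Rnr2 and mt-Nd2 fall outside the rule and were added after their values were seen. From the other parts the text gives examples. The correlations between neighbouring positions, the pairs of sites, the abundant clusters, the single-position clusters, the upstream CLIP windows and the empty mitochondrial stretch were chosen after seeing the data.

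The ratio was tested on simulated data, with Poisson counts at the 16684 clusters of the comparison of the oligos and 200 of them changed. The interval excluded 1 in the right direction for 78.5% of clusters changed 2-fold and 100% of those changed 4-fold, and for 3.68% and 3.80% of unchanged clusters. The simulation holds no noise from library preparation. For the CLIP density, planted ratios of 1, 2 and 4 at 12724 clusters came back as 1.00, 1.99 and 4.02. Alternatives changed the cluster gap, the read minimum, the thinning, the pseudocount, the counting of positions or reads, the A-rich rule, the alignment end used for CLIP, the CLIP windows and flanks, and left out each CLIP replicate or the mitochondrial clusters.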

Results

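Polyadenylated 3′ ends of mouse RNA were mapped by 3'READS, a method that captures poly(A)-containing fragments of RNA on beads and sequences them to locate the cleavage position. RNA from a commercial mix of 11 mouse cell lines was captured with 2 kinds of bead, 1 library each. The CU5T45 oligo carries 5 U and 45 T, and fragments bound to it were washed stringently and released with RNase H. The oligo(dT)10-25 beads carry the shorter and mixed T stretches of regular poly(A) selection. The same labels describe CLIP-seq of CstF64, the RNA-binding subunit of the cleavage stimulation factor that recognises U- and GU-rich sequence beside poly(A) sites. It was carried out in proliferating C2C12 cells, a mouse myoblast line, and is given as 2 replicates.

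The CU5T45 library held 6738355 reads at 236029 positions, and 50.8% of these positions had 1 read. The oligo(dT)10-25 library held 3482826 reads at 180853 positions, of which 54.2% had 1 read. The CLIP files held 1101047 and 1352122 distinct alignments, from 1185658 and 1546401 reads. With 1 library per oligo there is no replicate error, so each interval given for them covers counting error only, and the comparison is between these libraries, not the conditions. PCR copies are not independent molecules, so counting intervals are too narrow. A count of 0 allows up to 3 reads, which is 0.445 CPM (counts per 1e6 reads) in the CU5T45 library and 0.861 CPM in the oligo(dT)10-25 library. Nuclear sites are named by their position in the mm9 build of the deposited files, because no annotation of that build was used here, and mitochondrial genes by their symbols.

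The first comparison asks whether both oligos captured the same cleavage sites. Nearly all captured RNA came from sites seen with both. Positions chained within 24 nt formed 56206 clusters with at least 3 reads over both libraries, which held 98.7% of all reads. After the CU5T45 library was thinned to the depth of the other, it held 49399 clusters and the oligo(dT)10-25 library 50157. Of these, 88.6% (95% exact interval 88.4 to 88.9) and 87.3% (87.0 to 87.6) were shared, and the shared clusters held 99.6% and 99.3% of the reads. Clusters seen with 1 oligo alone were mostly small. At full depth, with the larger CU5T45 library not thinned, 6049 clusters were seen in CU5T45 alone and 2300 in oligo(dT)10-25 alone. These numbers therefore also reflect depth. Among clusters of 10 or more reads there were 230 and 180, beside 28077 seen in both. Requiring 10 reads per cluster left 28095 and 28257 clusters and raised the shared parts to 99.2% and 98.6%. The minimum counts the reads of both libraries together, and a cluster with more reads is less often missed in 1 library by sampling. Part of this rise is therefore built in, and its size was not estimated.

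Both oligos also placed the cleavage position at the same nucleotide. Among 3903 nuclear clusters with at least 100 reads in each library, the most used position was identical in 3639 (93.2%, interval 92.4 to 94.0) and within 2 nt in 94.9%. These clusters spanned a median of 23 nt and 8 positions. The most used position held a median of 75.8% of the CU5T45 reads of a cluster and 76.1% of its oligo(dT)10-25 reads.

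The second comparison asks whether the oligos measured the same abundance at each site. Most clusters with enough reads for a ratio lay within 2-fold, while many, abundant ones among them, differed by more than counting error. Across the 56206 clusters, which are not independent replicates, log2(CPM + 1) had a Pearson correlation of 0.914 and a Spearman correlation of 0.698. With each position counted once in place of its reads, a different set of 38602 clusters passed the minimum. Their numbers of positions had a Pearson correlation of 0.459. Of 16684 clusters with 30 or more reads, 4592 had a higher share of CU5T45 reads with an interval of the ratio above 1, 3915 a lower share, and 8177 an interval that included 1. Within 2-fold lay 73.4% of them, and the SD of the log2 ratio was 1.10. A 4-fold higher share in CU5T45 was found at 292 clusters and a 4-fold lower share at 753. Thinning CU5T45 to the depth of the other library, an alternative chosen after seeing the data, gave 184 higher and 718 lower. With each position counted once, only 292 clusters had the 30 positions then needed for a ratio, and 0 of these were 4-fold higher and 1 was 4-fold lower.

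**Figure D1:**
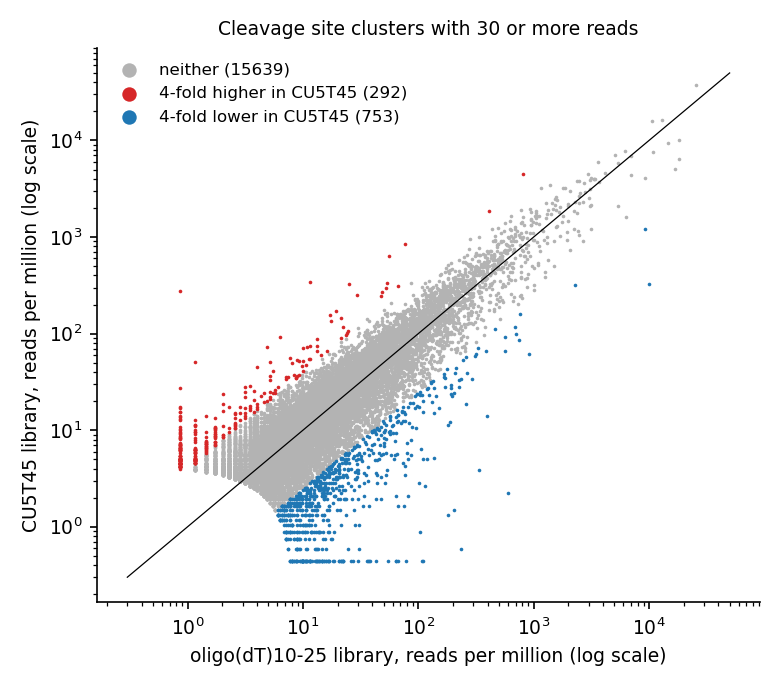
CPM of the 16684 clusters with 30 or more reads in the oligo(dT)10-25 library (x axis, log scale) and the CU5T45 library (y axis, log scale), each point a cluster, with counts under 3 drawn at 3 and the line of equal values in black. The 753 clusters called 4-fold lower in CU5T45 lie below the line and the 292 called 4-fold higher above it.

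The site with most reads, on the minus strand of chromosome 15 at 100504852, had 251248 CU5T45 and 88572 oligo(dT)10-25 reads, a ratio of shares of 1.47 (1.45 to 1.48). The next nuclear sites were chromosome 15 at 78021908, minus strand, at 1.26 times the oligo(dT)10-25 share, and chromosome 11 at 67073943, plus strand, at 1.52 times. Chromosome 7 at 20274829, minus strand, was 1.56-fold lower in CU5T45, and chromosome 5 at 90905627, plus strand, 2.85-fold lower. Large differences also occurred at abundant sites, singled out after their values were seen. Of 114 nuclear clusters with 10000 or more reads, 10 were at least 2-fold higher in CU5T45 and 12 at least 2-fold lower. Chromosome 5 at 88757838, plus strand, had 2182 CU5T45 and 35002 oligo(dT)10-25 reads, 31.0-fold lower (29.7 to 32.4). In the other direction, chromosome 7 at 133589373, minus strand, had 30191 and 2791 reads, 5.59-fold higher (5.38 to 5.81).

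Counts of 0 were set to 3 reads while counts of 1 or 2 were kept, so a site with 0 reads can rank behind one with 1 read. The order and range of the highest and lowest ratios depend on this floor. None of the 16 clusters without oligo(dT)10-25 reads, with up to 116 CU5T45 reads, is among the 12 highest. Among the 12 highest ratios, which ran from 24.6 to 951, chromosome 1 at 137648808, plus strand, had 1840 CU5T45 reads and 1 oligo(dT)10-25 read (ratio 951, interval 170 to 37584). Chromosome 2 at 73746503, minus strand, had 2293 and 40 reads, 29.6-fold higher (21.7 to 41.6). Chromosome 12 at 86640463, minus strand, had 183 reads and 1 read (ratio 94.6, interval 16.8 to 3756). At the other end, the 12 lowest ratios ran from 745-fold lower in CU5T45 at chromosome 11, position 48564209, minus strand (1 and 385 reads, interval 133 to 29496), to a site without CU5T45 reads on the plus strand of chromosome 7 at 127755051 (0 and 221 reads; at least 142.5-fold lower against a floor of 3 reads, and 115-fold by the lower limit of the exact interval). Chromosome 10 at 32976942, plus strand, had 15 and 2103 reads, 271-fold lower (164 to 486), and chromosome 4 at 97569699, plus strand, 4 and 824 reads, 399-fold lower (155 to 1466). Chromosome 12 at 98613447, plus strand, had 0 and 375 reads, at least 241.8-fold lower against that floor and 196-fold by the lower limit of the exact interval.

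Clusters made of a single position were more frequent among the sites lower in CU5T45. They made up 7 of the 12 lowest and 0 of the 12 highest. Of all clusters 4-fold lower in CU5T45, 20.3% (interval 17.5 to 23.4) had a single position, against 8.22% (5.34 to 12.0) of those 4-fold higher and 3.66% (3.37 to 3.97) of the rest. Median reads were 66 in the 4-fold lower and 61 in the 4-fold higher clusters, against 110 in the rest. The comparison with the rest is therefore not matched on reads. Without single-position clusters, 268 were 4-fold higher and 600 lower.

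The ratio between the libraries was shared in part by positions up to 24 nt apart, and not by those 25 to 100 nt apart. For positions with 30 or more reads, log2 ratios of neighbours 1 nt apart had a Pearson correlation of 0.744 (bootstrap interval 0.718 to 0.768; 2191 pairs). It was 0.503 (0.443 to 0.561) at 6 to 10 nt and 0.388 (0.287 to 0.470) at 11 to 24 nt. At 25 to 100 nt it was 0.00605 (-0.0754 to 0.0929; 460 pairs). For 2581 pairs of adjacent nuclear clusters on the same strand 400 to 5000 nt apart it was 0.0273 (-0.0147 to 0.0763). In these pairs, the distal site had the higher CU5T45 ratio in 47.0% (45.1 to 49.0), and the distal minus the proximal log2 ratio had a median of -0.09 (-0.17 to -0.03). Positions and pairs are not independent replicates. Positions 25 to 100 nt apart can still lie in the same cluster, chained by positions with fewer reads.

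**Figure D2:**
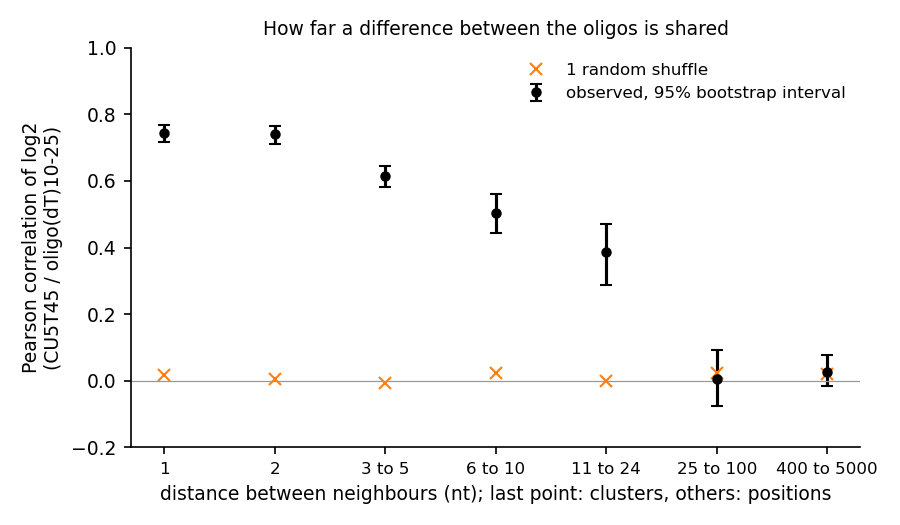
Pearson correlation (y axis) of the log2 ratio of CU5T45 to oligo(dT)10-25 shares between neighbouring positions, and in the last point between adjacent clusters, by distance in nt (x axis), with 95% bootstrap intervals and 1 random shuffle of the pairs as orange crosses. The correlation falls from 0.744 at 1 nt to 0.00605 at 25 to 100 nt.

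Mitochondrial RNA was captured less with CU5T45. Mitochondrial positions took 2.74% (2.73 to 2.76) of the CU5T45 reads and 5.57% of the oligo(dT)10-25 reads, 2.03-fold lower (2.02 to 2.04). With each position counted once they took 2.00% and 2.50% of positions. The CU5T45 library had more mitochondrial positions (4722 against 4529) and more positions in total (236029 against 180853). Its lower share of positions comes from the larger total and is no measure of capture. Of the list of 15 mitochondrial mRNAs and rRNAs, 6 had 30 or more reads within 10 nt of their annotated 3′ end, and all 6 were lower in CU5T45 with intervals that excluded 1. The ends of the ribosomal RNAs fell most. The end of mt-Rnr2, the large ribosomal RNA, was 4.70-fold lower (4.46 to 4.95), with 2098 and 5095 reads. That of mt-Rnr1, the small ribosomal RNA, was 4.50-fold lower (4.39 to 4.62), with 7854 and 18280 reads. Among mRNAs, mt-Cytb, which encodes cytochrome b of respiratory complex III, was 3.84-fold lower (3.79 to 3.90). The mRNAs of 3 subunits of complex I fell less, mt-Nd1 by 1.72-fold (1.70 to 1.75), mt-Nd4 by 1.52-fold (1.48 to 1.56) and mt-Nd2 by 1.32-fold (1.26 to 1.38). The median log2 ratio of the 6 ends was -1.36, at percentile 0.01 of 10000 random lists of nuclear clusters matched on reads, whose median was 0.34. The 6 ends belong to 1 genome whose reads were lower as a whole, so they are not independent draws. The percentile is therefore a description and not a test. Counting each position once gave a median of -0.39. This divides by the total of positions in each library, and equal numbers of positions at an end would already give a negative value. Its sign therefore decides nothing. Counting genes with 10 or more reads gave -0.69, as it added mt-Co3 (8 and 4 reads, interval of the ratio 0.277 to 4.69) and mt-Nd3 (9 and 2 reads, interval 0.481 to 22.1). These are among 7 genes that end in a stretch of the mitochondrial genome with few reads of either library. The other genes under 30 reads, mt-Nd5 (3 and 2 reads) and mt-Nd6 (1 and 6 reads), end outside it.

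Reads away from annotated ends also differed, and not all in that direction. Those on the plus strand were 1.47-fold lower in CU5T45 (1.45 to 1.49) and those of the largest minus-strand cluster, from 15984 to 16242 with its peak at 16163, 1.17-fold lower (1.14 to 1.20). Inside mt-Rnr2, reads away from the end had a CU5T45 to oligo(dT)10-25 ratio of 0.405 (0.394 to 0.416), a larger fall than at the ends of the complex I mRNAs. Inside mt-Nd2 the ratio was 0.664 (0.627 to 0.703), below the 0.758 (0.723 to 0.795) of its own end, and inside mt-Nd1 0.728 (0.702 to 0.754). It was closer to 1 inside mt-Cytb, at 0.931 (0.893 to 0.970), and mt-Rnr1, at 0.962 (0.936 to 0.988), and above 1 inside mt-Co1, at 1.15 (1.09 to 1.22). The 3 single positions with most reads away from ends, looked at after the data were seen, also went both ways. Position 606, in mt-Rnr1, was 1.67 times as high in CU5T45 (1.58 to 1.75), with 6190 and 1920 reads. Position 3844 had a ratio of 0.871 (0.818 to 0.927), and position 11657, in the tRNA gene mt-Ts2, was 2.36-fold lower (2.20 to 2.53).

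**Figure D3:**
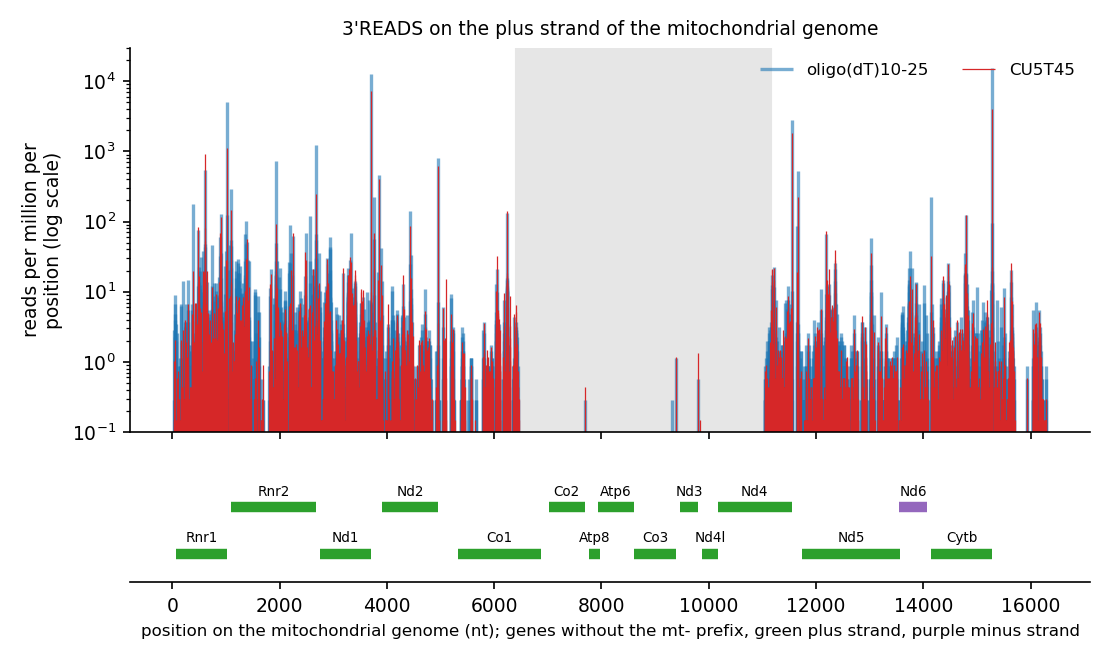
CPM at each position of the plus strand of the mitochondrial genome (y axis, log scale; x axis, position in nt) for oligo(dT)10-25 in blue and CU5T45 in red, above the genes of the list. In both libraries the ends of mt-Nd1 and mt-Cytb hold the most reads of the 6 measured ends, and the shaded stretch from 6408 to 11165 holds 292 CU5T45 and 265 oligo(dT)10-25 reads.

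The CU5T45 capture is meant to avoid internal A-rich stretches of RNA. A-rich flanks were counted on the mitochondrial genome only, for plus-strand reads away from annotated ends, and nuclear sequence was not analysed here. A flank of 7 A in a row or 8 A among 10 followed 0.0280% of CU5T45 reads (0.0163 to 0.0449; 17 of 60628) and 0.0301% of oligo(dT)10-25 reads (0.0165 to 0.0505; 14 of 46480), so no difference was detectable at this depth. Such flanks follow 0.637% of the positions with known sequence. With 6 in a row or 7 of 10 the shares were 0.493% (0.439 to 0.552) and 0.747% (0.670 to 0.829), lower in CU5T45 with separate intervals. Flanks of this kind follow 2.81% of the positions. Ratios inside genes ran from 0.405 in mt-Rnr2 to 1.15 in mt-Co1, and the place of these flanks was not taken into account. A filter for untemplated A, if used before deposition, would have removed internal A-rich capture. These shares therefore cannot decide whether CU5T45 avoids it.

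The third comparison asks where CstF64 was crosslinked relative to the mapped cleavage sites. Before it, the CLIP replicates were compared with each other. Of the alignments shorter than 50 nt, 90.8% of those in replicate 1 were also in replicate 2, and the counts within 100 nt of 6400 clusters had a chi-square of 0.232 per degree of freedom. The replicates thus differed by less than the sampling noise and were counted as 1 sample. Counted by reads, at 6924 clusters, the chi-square was 0.357 per degree of freedom. Both values argue against the replicates being independent draws of molecules. Whether they were made from separate cultures or from 1 library is not given in the sources used here, so their likeness is no measure of replication. Their correlation across clusters was 0.978 (Pearson) and 0.967 (Spearman), and 20941 of the 22319 clusters with an alignment in either had one in both. No control library was among the samples used, so the opposite strand and the flanking sequence served as background.

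CstF64 alignments gathered on both sides of the cleavage site on the transcribed strand. Over all 56206 clusters, from 0 to 40 nt downstream of the most used position, the density of alignment midpoints over the density 200 to 400 nt away was 2.48 (bootstrap interval 2.34 to 2.62) in replicate 1 and 2.41 (2.29 to 2.53) in replicate 2, with a mean of 2.44. The same ratio on the opposite strand was 1.43 (1.19 to 1.74) and 1.38 (1.17 to 1.63). From 40 nt upstream to the site it was higher, 3.05 (2.88 to 3.22) and 3.03 (2.87 to 3.17), with 1.00 and 1.01 on the opposite strand. At nuclear clusters the highest 10 nt bin lay 20 to 11 nt upstream, at 3.60 and 3.59. Against the downstream flank alone, chosen after seeing the data, the downstream mean was 2.47. The order of both sides and the place of the peak hold for midpoints of alignments of median length 35 and 36 nt. With alignments placed by their 5′ end the downstream mean was 2.08, and by their 3′ end 2.94. The window from 40 nt upstream was not run by either end, so the order of the sides was not tested there. Of the alignments centred within 60 nt of a site, 39.4% and 39.3% ended upstream of it, 27.8% and 28.0% spanned it, and 32.8% and 32.7% lay downstream.

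**Figure D4:**
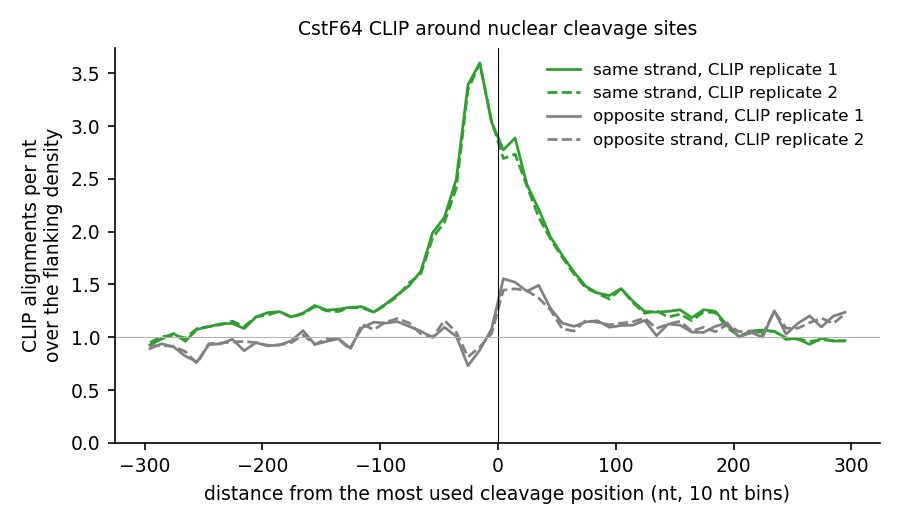
CstF64 CLIP alignment midpoints per nt, divided by the density 200 to 400 nt away (y axis), in 10 nt bins around the most used position of nuclear cleavage site clusters (x axis, nt, negative upstream), for the same strand in green and the opposite strand in grey, with a solid line for replicate 1 and a dashed line for replicate 2. The same-strand curves peak at 3.60 and 3.59 in the bin 20 to 11 nt upstream.

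More abundant sites had more CstF64 alignments, which were not divided by the amount of RNA in the C2C12 cells. The Spearman correlation of alignments with reads across nuclear clusters, which are not independent replicates, was 0.222 and 0.223. In the lowest tercile of nuclear clusters by reads 28.3% and 29.5% had an alignment within 100 nt, in the middle tercile 34.8% and 35.9%, and in the highest tercile 50.5% and 51.7%. The downstream density ratio was 1.94, 2.07 and 3.15 in these groups, as means of the replicates. In adjacent pairs of sites with different CLIP counts, the distal site had more alignments in 55.9% (52.7 to 59.1) and 54.9% (51.7 to 58.1) of pairs where it also had more reads. It did so in 37.7% (34.3 to 41.3) and 39.0% (35.6 to 42.5) of pairs where the proximal site had more reads. Mitochondrial ends, which are formed without the nuclear cleavage machinery, showed no such rise. At the 6 measured ends the downstream ratio was 0.0570 (0.0209 to 0.125) and 0.0959 (0.0477 to 0.172), from 6 and 11 alignments, and the upstream ratio was 0.789 and 0.802. The amount of RNA in the windows and flanks of these ends was not taken into account, so the ratios are no control for the nuclear rise.

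Most CstF64 alignments lay away from mapped sites. Within 100 nt of a cluster lay 9.78% (9.72 to 9.83) and 9.47% (9.42 to 9.52) of alignments on the same strand, against 1.09% and 1.06% on the opposite strand. Within 400 nt these were 17.4% and 17.2% on the same strand. Of the 20 clusters with most alignments, 6 lay within 1 stretch of the plus strand of chromosome 17, from 39983474 to 39985167. The first of them, at 39984726, had 1517 and 1478 alignments and 347 CU5T45 and 134 oligo(dT)10-25 reads. Its reads were spread over 73 positions from 39984689 to 39984862. Nuclear clusters with at least 100 reads in each library had a median of 8 positions. Chromosome 19 at 5798340, minus strand, followed with 1083 and 1259 alignments beside 47 and 37 reads. Mitochondrial position 1923, inside mt-Rnr2, had 406 and 403, and chromosome 11 at 106362524, plus strand, 358 and 353. Without a control library, whether the counts at these 20 clusters exceed background was not tested. Farther than 1000 nt from any cleavage cluster, the largest CLIP cluster lay on the plus strand of chromosome 14, from 66918848 to 66919391, with 306 and 340 alignments. The next, on the minus strand of chromosome 8 from 72085384 to 72085514, had 235 and 273 and lay 48887 nt from any cleavage cluster.

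CLIP gave a measure of clusters seen with 1 oligo alone that does not depend on the oligos, but the classes depend on depth. They were set without thinning, at 6738355 CU5T45 and 3482826 oligo(dT)10-25 reads. Sampling alone can therefore miss a cluster more often in oligo(dT)10-25 than in CU5T45. A difference between the classes seen with 1 oligo alone cannot be told apart from this difference in depth. Among clusters with 10 or more reads, 46.9% of those seen in both libraries had a CLIP alignment within 100 nt, as a mean of the replicates. This was 36.1% of the 230 seen in CU5T45 alone (29.5 to 42.2 in replicate 1, 30.3 to 43.1 in replicate 2) and 20.0% of the 180 seen in oligo(dT)10-25 alone (13.5 to 25.4 and 15.4 to 27.8). Clusters seen in both libraries had a median of 41 reads, against 12 and 14.5 in the other classes, so their higher share is not matched on reads. On the opposite strand the means were 7.31%, 5.65% and 1.11%. With 2 or more reads required near a cluster, an alternative chosen after seeing the data, the intervals of clusters seen with 1 oligo alone overlapped (19.7 to 31.3 and 9.19 to 19.8 in replicate 1). At 3 to 4 reads the shares were 29.0%, 28.5% and 24.1%, and the intervals of clusters seen in CU5T45 alone (26.7 to 29.3 in replicate 1) and in oligo(dT)10-25 alone (21.7 to 25.9) were also separate. At 5 to 9 reads the shares were 32.9%, 30.2% and 26.4%, and these intervals overlapped. The CLIP came from C2C12 cells and the clusters from a mix of cell lines, so a cluster without CLIP need not be unused.

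**Figure D5:**
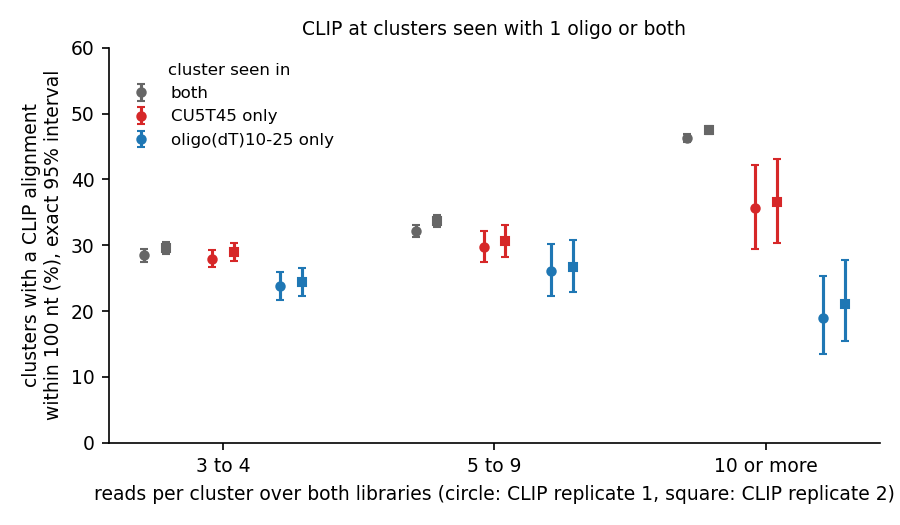
Percent of clusters with a CstF64 CLIP alignment within 100 nt (y axis, with exact 95% intervals) by reads per cluster (x axis) for clusters seen in both libraries (grey), in CU5T45 alone (red) and in oligo(dT)10-25 alone (blue), with circles for replicate 1 and squares for replicate 2. The classes were set without thinning. At 10 or more reads the means are 46.9%, 36.1% and 20.0%.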

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

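All tests of explanations in this part were chosen after the result was seen. CstF64 CLIP gave 812 alignments in replicate 1 and 904 in replicate 2 on the plus strand of chromosome 14 between 66908848 and 66929391, around the largest CLIP cluster over 1000 nt from any cleavage cluster, against 1 and 1 on the opposite strand. This was looked at because the cluster itself, with 306 and 340 alignments, lay 4668 nt from the nearest cleavage cluster; the window reaches 10000 nt to each side and also held 189 CU5T45 and 66 oligo(dT)10-25 reads. CLIP also gave 4325 and 4808 alignments on the mitochondrial genome, 0.393% and 0.356% of all alignments, outside the nuclear RNA that the cleavage stimulation factor acts on. They were looked at only because they are above the 3 that a count of 0 allows, and with no control library whether they exceed background was not tested.

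Ratios of CU5T45 to oligo(dT)10-25 differed from site to site, although both labels name the same mix of cell lines, and no biological explanation was tested for this or the following patterns. A different RNA composition of the libraries, as the whole cause, would give neighbouring sites of a transcript the same ratio, but log2 ratios 25 to 100 nt apart had a correlation of 0.00605 (-0.0754 to 0.0929). Few amplified molecules behind each site, as the whole cause, would leave positions 11 to 24 nt apart uncorrelated if such ends are different molecules, but pairs in which each had at least 50% of the reads of the other had a correlation of 0.454 (0.303 to 0.597); at single-position clusters, 153 of those 4-fold lower, few molecules cannot be told apart from other explanations, as molecules were not counted. Ends that are not cleavage sites cannot be told apart from regions with less CLIP in general, for single-position clusters: of the single-position clusters 4-fold lower in CU5T45, 20.3% (14.2 to 27.5) had CLIP within 100 nt, against 229 of 573 single-position clusters (35.9 to 44.1%) without a 4-fold difference, but the share was also lower on the opposite strand (1.31% against 6.28%) and at clusters of 2 or more positions (47.8%, 43.8 to 51.9, against 54.7%, 53.9 to 55.5). Capture that depends on the sequence or tail beside each site stays open, since neither was measured here.

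Mitochondrial 3′ ends were lower in CU5T45. A lower mitochondrial RNA content, as the whole cause, would move all mitochondrial positions by 1 factor. The ratio at annotated ends was instead 0.584 (0.576 to 0.593) of the ratio elsewhere on the plus strand. At mt-Nd2 the order was the other way (0.758 at its end, 0.664 inside). A lower content as part of the fall stays open, since plus-strand reads elsewhere were also lower in CU5T45 (ratio 0.681, 0.672 to 0.689). Internal A-rich capture by oligo(dT)10-25 needs A-rich sequence after the ends, and 0 of the 5 measured ends with known flanks had 6 A in a row or 7 of 10. Short poly(A) tails lost in the wash of the CU5T45 beads are a candidate explanation that cannot be told apart from others, since tail lengths were not measured; the folds of the 6 ends differed up to 3.56-fold, with the ribosomal RNAs fallen most.

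The plus strand of the mitochondrial genome held few reads from 6408 to 11165, a stretch with the 3′ ends of 7 genes, mt-Co1, mt-Co2, mt-Atp8, mt-Atp6, mt-Co3, mt-Nd3 and mt-Nd4l. It took 292 CU5T45 and 265 oligo(dT)10-25 reads, and 17 and 19 CLIP alignments. Reads shared with nuclear copies and left out by the alignment may explain part of it: 85.0% of its 72 nt words also lie in transcripts annotated outside the mitochondrial genome, among them Gm28439, Gm28437 and Gm10925, against 3.06% of the words outside. Inside the stretch, 0.0275% (0.000696 to 0.153) of positions whose last 72 nt are shared had a read, against 13.1% (10.7 to 15.8) of the others, which shared 72 nt words leave open, as 41.8% (40.9 to 42.8) of positions not shared had a read outside the stretch. At the gene ends themselves, reads shared with nuclear copies cannot be told apart from other explanations: only 3 of the 7 ends share their last 36 nt, those of mt-Co1, mt-Co2 and mt-Atp8, while the other 4 had at most 12 reads, as had mt-Nd5 outside the stretch with 5 reads and no shared 72, 36 or 25 nt, and nuclear sequence outside transcripts was not searched.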

How the results depend on the processing

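The alternatives named below as added, and their tests, were chosen after the result was seen. Of 109 alternatives, 53 stayed within the interval of the reported value (for a count, within 1.5 times) and 56 moved it further. A turn of direction was looked for only in the median log2 ratio of mitochondrial ends, where none occurred. With each position counted once, the larger total of CU5T45 positions alone can make that median negative, so this alternative decides nothing. The cause was not tested unless given. A minimum of 10 reads left 28095 CU5T45 and 28257 oligo(dT)10-25 clusters, since fewer clusters pass it. The shared part of CU5T45 clusters was 88.0% with a gap of 10 nt, 89.1% with 50 nt, 96.6% with each position counted once, 77.9% at 2 reads and 99.2% at 10 reads. For oligo(dT)10-25 it was 94.7% with each position counted once, 77.0% at 2 reads, 98.6% at 10 reads and 95.4% without thinning.

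The Pearson correlation of abundance was 0.912 and 0.917 with gaps of 10 and 50 nt, 0.945 with 10 CPM added and 0.893 at 10 or more reads. With each position counted once, over 38602 clusters, it was 0.459. Added alternatives gave 0.926 without single-position clusters and 0.908 with CU5T45 thinned. Clusters 4-fold higher in CU5T45 numbered 0 and those 4-fold lower 1 with each position counted once; thinning CU5T45 (added) gave 184 higher. The median log2 ratio of mitochondrial ends was -0.69 for genes with 10 or more reads and -0.39 with each position counted once. A-rich flanks followed 0.493% of CU5T45 and 0.747% of oligo(dT)10-25 reads as 6 in a row or 7 of 10, and 0.0551% and 0.0592% with each position counted once. Mitochondrial shares were 2.00% and 2.50% with each position counted once, where the larger total of CU5T45 positions lowers its share. They were 1.22% and 1.72% without annotated ends (added).

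The downstream CLIP density ratio was 2.24 at 2 reads, 2.73 at 10 reads, 2.08 by the 5′ end and 2.94 by the 3′ end of alignments. It was 1.91 over 0 to 100 nt, 2.19 over 100 nt upstream, 3.25 against flanks at 500 to 1000 nt, 2.85 at clusters with 10 or more CU5T45 reads and 3.45 at clusters with no other within 400 nt. The correlation between CLIP replicates was 0.984 with 10 CPM added and 0.975 with every read (added). The CLIP share near sites was 9.47 to 9.78% with 1 replicate left out, which tests little as the replicates may be 1 library, 11.0% at 2 reads, 7.24% at 10 reads, 6.61% within 40 nt and 17.3% within 400 nt. Added alternatives gave 11.2% with every read and 9.21% without the locus of most alignments. With every read and 2 or more per cluster (added), CLIP lay at 27.0% of clusters of 10 or more reads seen in CU5T45 alone and 16.1% of those seen in oligo(dT)10-25 alone, with intervals that overlapped in each replicate. Over all read numbers it lay at 19.0% of CU5T45-only and 15.7% of oligo(dT)10-25-only clusters, against 29.2% and 24.3% with distinct alignments. Without that rule it was 26.5% of CU5T45-only clusters at 2 reads, and 36.1% and 20.0% at 10 reads. No paired analysis was possible because the oligos had 1 library each. Nuclear poly(A) signals, nuclear A-rich flanks, nuclear annotation classes and the lists of nuclear genes were not run, for want of a reference of the mm9 build here, and the lists without mitochondrial genes left no member.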
